A study of Mus musculus with 15 samples.

How the data were processed

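Foam cells were studied in 15 samples of mice lacking apolipoprotein E, in 3 groups of 5: regular chow (CHOW), a western-type diet for 2 weeks (2w-WD) and the same diet for 14 weeks (14w-WD). Per the labels' protocols, macrophages of lesions were taken by laser-capture microdissection, their RNA was extracted with the PicoPure kit and amplified with the RiboAmp HS kit, and 15 µg of amplified RNA were labelled with biotin by the TURBO kit for hybridisation to Affymetrix whole-genome mouse arrays. The deposited table holds 1 intensity on a linear scale for each of 45037 probe sets and each array. How the authors summarised, background-corrected and normalized these intensities is not given in the sources used here. Each array had 991 to 1238 values at exactly 1 and only 3 to 25 below it, and array medians lay between intensities of 31.7 and 38.2. No 2 arrays held identical columns, and the correlation of log2 values between pairs of arrays ran from 0.862 to 0.972.

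The labels do not tie arrays to animals, so p-values here measure only the spread between these samples, which may be technical in part. Replicate numbers were taken from the sample titles. For arrays no counting depth exists; the number of arrays and the brightness of a probe set above background limit the precision.

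Probe sets were named through the GEO annotation of the array: 34945 had 1 gene, 932 had several and 9160 were unnamed here. Of the named ones, 34741 matched the mouse gene table of assembly GRCm38.p6 by gene number, and 0 symbols needed an update. No coordinates were used. Intensities were turned into log2(intensity + 16), so that a fold change is on this scale and understates the change of dim genes. Each of 18193 genes was represented by the probe set with the highest mean over the 15 arrays, as 9010 genes had more than 1. Genes whose mean lay below the median of all probe sets (log2 5.66, an intensity of 34.6) were left out, which kept 11925 genes. The design had foreseen deposited log2 values; the values were linear, so the log2 step and the pseudocount foreseen for that case were used.

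Gene tests used limma 3.58.1 (lmFit and eBayes with an intensity trend) in R 4.3.3 on all 15 arrays, with the 3 pairwise contrasts, the mean of both western diet groups against CHOW, and an F test over the 3 groups. A gene counted as changed at a Benjamini-Hochberg adjusted p under 0.05 over the genes tested. Printed SEs are those of limma, and all tests were two-sided. Before the data were examined, 34 gene lists were fixed, 22 of processes and 12 of cell types. The process lists were guanylate-binding proteins, immunity-related GTPases, type I interferon response, MHC class I and MHC class II presentation, inflammatory cytokines and NF-kB, chemokines and receptors, alternative activation, liver X receptor targets, sterol biosynthesis, lipoprotein uptake, lipid droplets, lysosome, lipid-associated macrophage, efferocytosis (the clearance of dead cells), unfolded protein response, oxidative stress, cell cycle, glycolysis and hypoxia, oxidative phosphorylation, matrix remodelling and immediate early genes. The cell type lists were macrophage, smooth muscle, endothelium, fibroblast, heart muscle, cartilage, T and NK cell, B cell, dendritic cell, neutrophil, adipocyte and erythroid. Lists share members (Ctsd and Ctsk, for instance, are in the lysosome and the lipid-associated macrophage list), and foam cells themselves express most of the macrophage and lysosome genes. The erythroid list had 2 tested members and was not tested. The other 33 lists had at least 5 and were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. Camera asks whether a list moved relative to all other tested genes. Beside it stand camera with an estimated correlation, fry, which asks whether the members move on balance in 1 direction, and an exact permutation test of the list's mean per array, whose smallest possible p with 5 against 5 arrays is 0.00794. The guanylate-binding protein list was chosen from knowledge of the study, which reported on these genes in these samples, so its direction is not independent evidence.

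Named genes followed a rule. For each pairwise comparison they were the 10 largest rises and 10 largest falls past the threshold, or, where fewer than 10 passed, all that passed, filled up to 5 by the smallest unadjusted p. In each list whose test passed they were the members past the threshold, or otherwise the 4 with the smallest unadjusted p, and in other lists up to 3 such members. Always named were Apoe, the measured guanylate-binding proteins, Cd68, Adgre1, Acta2, Pecam1, Myh6, Il1b, Tnf, Il6, Ccl2 and Abca1. Some items on the rule are not reported here, and genes with clone or predicted names were counted without a name unless a list held them.

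The gene test was tested on simulated data with 11925 genes drawn with the real means and spreads, 100 genes changed by a log2 of 1 and 100 by a log2 of 2. In 14w-WD versus CHOW it recovered 34% and 80% of them with 7 false calls, and in 14w-WD versus 2w-WD 33% and 84% with 3 false calls. The simulated genes were independent of each other and had no shifts common to an array. The false calls therefore do not measure those to be met on the real arrays, where genes vary together. Alternatives covered the scaling between arrays (quantile, median centring), the filter (none, or the 70th percentile), the pseudocount (1), the probe sets of a gene (their mean), the prior variance (no trend, robust), array weights, a fit of only the 2 groups compared, the replicate number as a block, an adjusted p under 0.10 and leaving out each array in turn. The planned 3-prime to 5-prime covariate needs control probe sets, of which the table used here has 0, and was not run. Per-array measures were compared by exact permutation tests. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for tables and plots.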

Results

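Foam cells, the lipid-laden macrophages of atherosclerotic lesions, were captured by laser from the aortic sinus of C57BL/6 mice that lack apolipoprotein E, and their amplified RNA was measured on 15 arrays. The groups were 5 samples from mice on regular chow (CHOW), 5 from mice given a western-type diet for 2 weeks (2w-WD) and 5 from mice given it for 14 weeks (14w-WD). Per the labels, the CHOW mice ate chow up to week 22, and the 14w-WD mice received the diet from week 8 to week 22. For 2w-WD the sample labels give 20 weeks of chow before the diet, whereas the series text places the diet from week 22 to week 24, so the age of this group is uncertain. The comparisons ask how lesional foam cells differ between chow, short and long western diet feeding.

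Macrophage and foam cell transcripts lay far above the filter level on every array. Adgre1, which encodes the macrophage marker F4/80, had log2 levels of 12.81 ± 0.19 (SD, n = 5) in CHOW, 12.79 ± 0.23 in 2w-WD and 12.93 ± 0.05 in 14w-WD. Abca1, the cholesterol exporter, stood at 12.45 ± 0.41, 12.55 ± 0.17 and 12.71 ± 0.07. Acta2, the smooth muscle actin gene, stood at 13.53 ± 0.30, 13.23 ± 0.09 and 13.17 ± 0.48. Myh6, the heart muscle myosin, stood at 13.31 ± 1.88, 14.44 ± 0.26 and 14.08 ± 0.42, with 9.98 on CHOW replicate 4. Averaged over all arrays, Apoe, the gene disrupted in these mice, lay below the level needed for testing (4.97 ± 0.56, 5.01 ± 0.30 and 5.34 ± 0.31). So did Gbp2b (4.57, 4.59 and 4.47), Pecam1 (5.07, 5.34 and 5.37), Tnf (5.45, 5.26 and 5.77) and Il6 (5.06, 5.38 and 6.47). In 14w-WD alone Tnf and Il6 lay above that level of 5.66, so their changes were left untested. Il6 stood at 7.06, 8.04 and 7.16 on 14w-WD replicates 1, 3 and 4, but at 5.71 and 4.39 on replicates 2 and 5. In no comparison did Adgre1, Abca1, Acta2, Myh6, Cd68, Il1b, Ccl2 or Gbp2 pass the gene test.

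The share of probe sets above an intensity of 100 was 21.7% ± 1.84 (SD, n = 5) in CHOW, 20.9% ± 2.86 in 2w-WD and 24.8% ± 1.80 in 14w-WD. The 14w-WD mean exceeded 2w-WD by 3.97 percentage points (exact permutation p = 0.0317) and CHOW by 3.14 (exact permutation p = 0.0397). Neither passed adjustment over the 9 per-array tests of 3 brightness measures (adjusted p = 0.0857 for both), and 2w-WD differed from CHOW by -0.83 (exact permutation p = 0.603). The highest 2w-WD array, replicate 1, had 25.7%, and the highest CHOW array, replicate 1, had 24.7%, against 22.5% to 27.2% in 14w-WD.

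In 2w-WD against CHOW, which asks what 2 weeks of the diet did, 0 of 11925 genes passed on their own. By camera at its preset correlation, the lysosome list (acid hydrolases and proton pump subunits) fell and the heart muscle list rose. The estimated inter-gene correlation was 0.508 for the lysosome and 0.537 for the heart muscle list, far above the preset 0.01. Their p-values at the preset are therefore likely too small. The 20 lysosome genes averaged a log2 level of 12.80 ± 0.11 (SD, n = 5) in CHOW and 12.31 ± 0.42 in 2w-WD. Their mean change was -0.50, with 17 of 20 members below 0 (adjusted p = 1.26e-06, and adjusted p = 0.77 with an estimated correlation). The 15 heart muscle genes averaged 9.79 ± 1.74 in CHOW and were higher in 2w-WD (SD 1.01) by a mean of 1.21 (adjusted p = 1.26e-06, and adjusted p = 0.77 with an estimated correlation). Gusb, a lysosomal glucuronidase (log2 change -2.09, SE 0.54), Atp6v1a, a subunit of the lysosomal proton pump (-1.62, SE 0.45), Lipa, the acid lipase that frees cholesterol from its esters (-0.61, SE 0.18), and the protease gene Ctsl (-0.39, SE 0.12) were the leading lysosome members. Over all genes tested each had an adjusted p of 0.480. Adjusted over the list alone, 9 lysosome members were lower and 0 higher. Without 2w-WD replicate 4, the array with the lowest lysosome mean, the list's change was -0.32 and still passed.

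Of the 33 lists, 9 passed in this comparison, 6 lower and 3 higher in 2w-WD, and for each of them the adjusted p was 0.77 with an estimated correlation. Genes of efferocytosis fell by a mean log2 of 0.52 (adjusted p = 0.00550, 17 of 20 below 0), while 0 single members passed adjusted over the list alone. Members with large negative values were C1qa and C1qc, which encode chains of the complement protein C1q (log2 changes -1.34 and -1.22), Itgb3 (-1.28) and the receptor kinase gene Axl (-0.83). Immediate early genes fell by 0.48 (adjusted p = 0.0199) with all 17 members below 0, and adjusted over the list alone 3 were lower: Atf3 (-1.50), Fos (-0.93) and Klf6 (-1.40), all transcription factors. The list no longer passed without CHOW replicate 5 (adjusted p = 0.234) or 2w-WD replicates 2 (0.0536) or 4 (0.0698). Genes of the unfolded protein response fell by 0.42 (adjusted p = 0.0410), with Creld2 (-1.31) and Manf (-1.09) lower adjusted over the list alone. It did not pass without CHOW replicates 4 or 5 or 2w-WD replicates 2, 3 or 4 (adjusted p from 0.0653 to 0.266). The lipid-associated macrophage list fell by 0.34 (adjusted p = 0.00550), with Cd9 (-1.40) and the cathepsin gene Ctsd (-0.46) lower adjusted over the list alone, beside Ctsk (-0.84) and Itgax (-0.48); without 2w-WD replicate 1 the adjusted p was 0.0782, and without 2w-WD replicate 4 the change was -0.21 and still passed. The macrophage list fell by 0.33 (adjusted p = 0.0235), with Mpeg1 (-0.34), Tyrobp (-0.28), Lyz2 (-0.26) and Cd68 (-0.76) as its leading members and 0 members past the test adjusted over the list alone, and it did not pass without CHOW replicate 2 (adjusted p = 0.104) or 2w-WD replicate 1 (adjusted p = 0.349). Genes of oxidative phosphorylation rose by 0.14 (adjusted p = 0.00385), with Cox5a (0.55), Cox6c (0.57), Ndufs8 (0.46) and Uqcrb (0.54) leading, but without 2w-WD replicate 1 the mean change was -0.09 (adjusted p = 0.478) and without 2w-WD replicate 2 it was 0.06 (adjusted p = 0.0653). Chemokines and their receptors rose by 0.18 (adjusted p = 0.0429), with the monocyte attractant Ccl2 (0.97), Ccl4 (0.79) and the receptor gene Ccr2 (1.15) above 0 and Cxcl12 (-0.40) below. Leaving out 1 array gave a chemokine mean of 0.08 (without CHOW replicate 5) to 0.28 (without CHOW replicate 4), and 6 single arrays ended the call.

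The heart muscle members with the smallest p were Ttn (log2 change 2.49, SE 0.83), Actn2 (2.14, SE 0.76), Myl7 (2.37, SE 0.91) and Tnnt2 (1.91, SE 0.76), genes of the contractile apparatus. CHOW replicate 4 held the lowest CHOW level of 13 of the 15 heart muscle genes, and without it the list's mean change was 0.47. The fall of the lysosome and macrophage lists came in the group whose heart muscle signal was higher. With the heart muscle mean as a covariate, chosen after seeing the data, the lysosome list still passed (-0.50, adjusted p = 2.67e-05), as did the efferocytosis, immediate early, lipid-associated macrophage and chemokine lists. The macrophage (-0.30) and unfolded protein response (-0.40) lists missed the threshold (adjusted p = 0.163 for both) with changes close to those without the covariate. The oxidative phosphorylation list, at -0.13, did not pass either, and against its own mean the change of the heart muscle list is 0 by construction.

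Among single genes, limma called 0 in 2w-WD against CHOW, with 1164 at an unadjusted p under 0.05, of which 294 were higher and 870 lower. The smallest adjusted p was 0.292, for Panx1, a membrane channel gene (log2 change -1.15, SE 0.21). The other genes with the smallest p on the lower side were Atf3, Il1rn, the interleukin-1 receptor antagonist (-1.63, SE 0.36), Fam102a (-1.18, SE 0.27) and Sptlc2, which encodes a subunit of the enzyme that starts sphingolipid synthesis (-1.47, SE 0.35). On the higher side they were Aamdc (1.42, SE 0.31), Gart, an enzyme of purine synthesis (1.65, SE 0.37), Cxcl13, a B cell attractant (1.78, SE 0.42), Pifo (0.81, SE 0.20) and Proser2 (0.67, SE 0.17). None of these 10 passed (adjusted p from 0.292 to 0.480), and no other gene-level setting run gave more than 0. The median change of all genes was -0.10. Under quantile normalization the macrophage (-0.28, adjusted p = 0.0578) and chemokine (0.30, adjusted p = 0.0719) lists no longer passed, nor did the chemokines with median centring (0.21, adjusted p = 0.0550), although the chemokine changes were larger than without these scalings. Per-array exact permutation of list means passed adjustment for 0 lists, with p = 0.0159 for the lysosome and 0.222 for the heart muscle list before adjustment, and fry called 0.

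**Figure D1:**
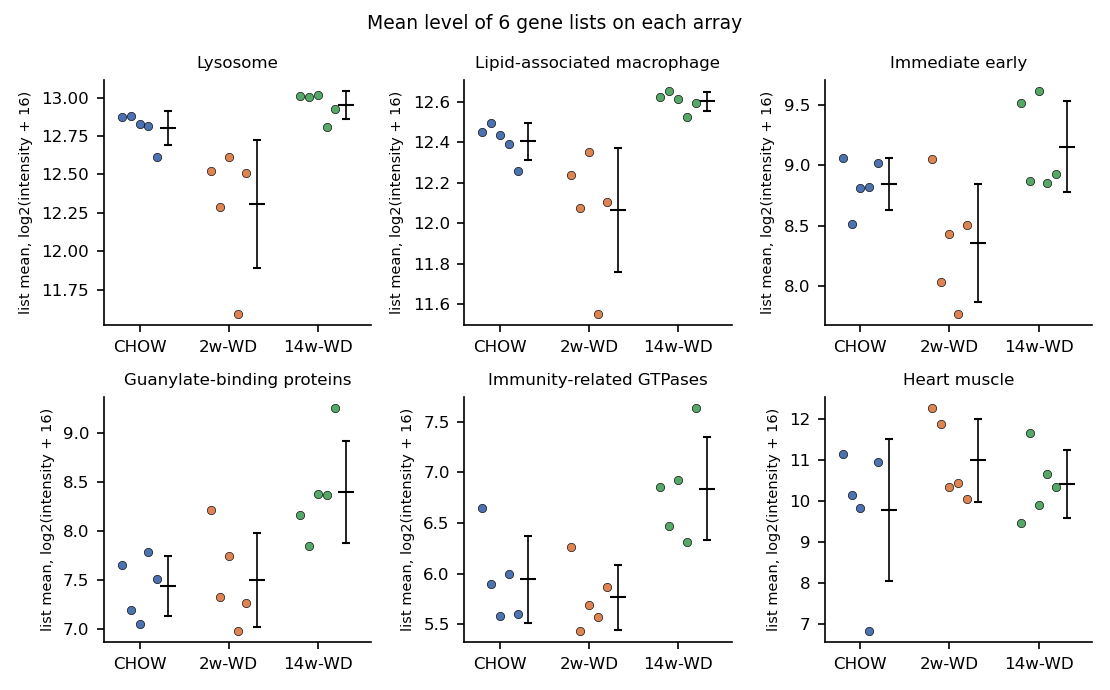
Mean log2(intensity + 16) of the members of 6 gene lists on each of the 15 arrays (points, coloured by group), with the group mean and SD (bars, n = 5). The lysosome and lipid-associated macrophage lists are lowest in 2w-WD, the guanylate-binding protein and immunity-related GTPase lists are highest in 14w-WD, and CHOW replicate 4 stands apart in the heart muscle list.

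In 14w-WD against CHOW, which asks what 14 weeks of the diet did, the guanylate-binding proteins and the immunity-related GTPases, both families of interferon-inducible GTPases that act in cell-autonomous defence, were higher. The 5 tested guanylate-binding protein genes averaged 7.44 in CHOW and 8.40 in 14w-WD, a mean log2 change of 0.96 with 5 of 5 above 0 (adjusted p = 0.0437, and adjusted p = 0.84 with an estimated correlation). Gbp6 was higher by 1.69 (SE 0.40, adjusted p = 0.0956) and Gbp3 by 1.61 (SE 0.41, adjusted p = 0.117), each with all 5 arrays of 14w-WD above all 5 of CHOW. A lack of overlap in either direction comes by chance in 0.794% of genes. The share over all genes tested was not counted in this comparison, but was 8.63% in 14w-WD versus 2w-WD, so 0.794% may understate how common it is. The intensity of Gbp6 lay below the filter level of 34.6 on all 5 CHOW arrays (3.38 to 33.2), so the size of its change depends on the pseudocount (2.47 with a pseudocount of 1, adjusted p = 0.152). Gbp7 (0.76, SE 0.42), Gbp8 (0.55, SE 0.24) and Gbp2 (0.20, SE 0.29) had smaller differences. Over all genes tested 0 of the 5 passed. Adjusted over the list alone 2 were higher, which is not independent evidence, since the study chose these genes on these samples.

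The 6 immunity-related GTPase genes averaged 5.94 ± 0.43 (SD, n = 5) in CHOW and 6.84 ± 0.51 in 14w-WD, a change of 0.89 with 5 of 6 above 0 (adjusted p = 0.0437 in limma, and adjusted p = 0.84 with an estimated correlation). The CHOW level lay little above the filter at 5.66, so the sizes of these changes depend on the pseudocount (mean 1.12 with a pseudocount of 1). Adjusted over the list alone 3 were higher: Gm4951 (log2 change 1.72, SE 0.43), Irgm2 (1.35, SE 0.34) and Ifi47 (1.13, SE 0.42). Igtp had 0.81 (SE 0.39). No other list passed. The closest was the cell cycle list (mean change 0.52, adjusted p = 0.0521), where Top2a, the DNA topoisomerase of dividing cells (1.31, SE 0.30), Rrm2 (1.10, SE 0.31) and Ccna2 (1.16, SE 0.38) were higher adjusted over the list alone. The type I interferon response list averaged 0.55 with 15 of 18 above 0 (adjusted p = 0.306). Adjusted over the list alone Ifit2 (2.53, SE 0.63) and Ifit1 (1.46, SE 0.41), which encode antiviral proteins, were higher, and Dhx58 (-0.74, SE 0.20) was lower. MHC class I genes averaged 0.57 with 10 of 10 above 0 (adjusted p = 0.249), chemokines and receptors 0.58 (adjusted p = 0.306) with Ccl8 at 2.31 (SE 0.72) and Cxcl9 at 1.74 (SE 0.59), and inflammatory cytokine and NF-kB genes 0.24 (adjusted p = 0.683). The lysosome list averaged 0.15 (adjusted p = 0.673), the lipid-associated macrophage list 0.20 (adjusted p = 0.614) and the heart muscle list 0.63 (adjusted p = 0.614).

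Among single genes, Galnt7, which encodes a glycosyltransferase of mucin-type sugar chains, rose by 1.63 (SE 0.22, adjusted p = 0.0140 in limma). Its log2 level was 5.74 ± 0.38 (SD, n = 5) in CHOW and 7.37 ± 0.33 in 14w-WD. Galnt7 was the 1 gene that passed. That count was 2234 with array weights, 1353 without the 3 arrays of lowest weight (chosen after seeing the data), 201 without 2w-WD replicate 1, 17 without CHOW replicate 1, 8 without 2w-WD replicate 4, 4 without CHOW replicate 4, and 0 without CHOW replicates 2, 3 or 5 or 14w-WD replicates 1, 3 or 5. At an unadjusted p under 0.05 there were 1893 genes, 1338 higher and 555 lower. The genes next to Galnt7 were Nin, a centrosome protein gene (log2 change 2.05, SE 0.34), Mfsd14b (1.36, SE 0.23) and Ankhd1 (1.73, SE 0.30), each with an adjusted p of 0.0548, and Cacybp (1.54, SE 0.27, adjusted p = 0.0597). On the lower side stood Hecw2 (-1.18, SE 0.22, adjusted p = 0.0803), Gatd1 (-1.52, SE 0.30, adjusted p = 0.0814), and Gata5os (-1.16, SE 0.25), Tex15 (-0.90, SE 0.19) and the sodium-calcium exchanger gene Slc8a3 (-0.86, SE 0.19), all 3 with an adjusted p of 0.0956. The median change of all genes in this comparison was 0.16, and 0.00374 under quantile normalization. Relative to the median gene the guanylate-binding proteins averaged 0.80 and the immunity-related GTPases 0.74.

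Both GTPase lists kept their direction under quantile normalization (0.77 and 0.75) and with the share of probe sets above 100 as a covariate (0.67 and 0.51, chosen after seeing the data). Neither passed with array weights (1.03 and 1.06, adjusted p = 0.171 and 0.0678) or when only the 2 groups were fitted (0.96 and 0.89, adjusted p = 0.101 for both). Neither did without a filter (0.78 and 0.77, adjusted p = 0.0649 for both) or with a pseudocount of 1 (1.19 and 1.12, adjusted p = 0.0602 for both). Both also missed the threshold with fry (adjusted p = 0.112 and 0.133) and by exact permutation (adjusted p = 0.0524 and 0.112). Their estimated inter-gene correlations, 0.417 and 0.400, were also far above camera's preset of 0.01. For the guanylate-binding proteins the unadjusted exact permutation p, 0.00794, was the smallest that test can give. The type I interferon response, glycolysis, lipid-associated macrophage and sterol biosynthesis lists reached the same exact permutation p, so it does not set the guanylate-binding proteins apart. Over all alternatives their adjusted p ran from 0.00717 to 0.836. Of single arrays, leaving out CHOW replicates 2 or 3, 2w-WD replicates 1, 3 or 4 or 14w-WD replicate 5 ended both calls, CHOW replicate 1 or 14w-WD replicate 4 that of the guanylate-binding proteins, and CHOW replicates 4 or 5 that of the immunity-related GTPases (adjusted p from 0.0528 to 0.278). Galnt7 missed the threshold under quantile normalization (adjusted p = 0.0521) and when its probe sets were averaged (log2 change 0.54, adjusted p = 0.154). The adjusted p of Galnt7 ran from 0.00133 to 0.271 over its alternatives.

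**Figure D2:**
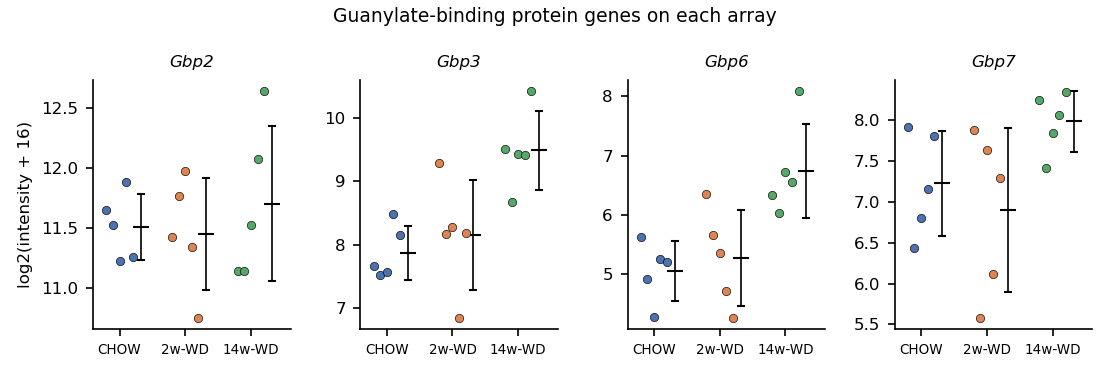
Log2(intensity + 16) of Gbp2, Gbp3, Gbp6 and Gbp7 on each array (points, by group), with the group mean and SD (bars, n = 5). For Gbp3 and Gbp6 all 14w-WD arrays lie above all CHOW arrays, while the groups overlap for Gbp2 and Gbp7.

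In 14w-WD against 2w-WD, which asks how long feeding differs from short feeding, 1338 of 11925 genes changed, 1201 higher and 137 lower in 14w-WD. By camera, lysosome genes and genes of lipid-associated macrophages rose and heart muscle genes fell. The 20 lysosome genes averaged 12.31 ± 0.42 (SD, n = 5) in 2w-WD and 12.95 ± 0.09 in 14w-WD, a mean log2 change of 0.65 with 19 of 20 above 0 (adjusted p = 0.000689, and adjusted p = 0.73 with an estimated correlation). The lipid-associated macrophage list averaged 12.06 ± 0.31 and 12.60 ± 0.05, a change of 0.54 with 16 of 16 above 0 (adjusted p = 0.0349, and adjusted p = 0.73 with an estimated correlation). The heart muscle list averaged 10.42 ± 0.83 in 14w-WD, a change of -0.58 from 2w-WD (adjusted p = 0.0349, and adjusted p = 0.73 with an estimated correlation) with 0 of its 15 members past the gene test. That change was -0.27 without 2w-WD replicate 1, -0.36 without 2w-WD replicate 2, -0.35 without 14w-WD replicate 1 and -0.46 without 14w-WD replicate 3, none of which passed (adjusted p from 0.0774 to 0.139), and -0.90 without 14w-WD replicate 2; the lipid-associated macrophage list did not pass without 2w-WD replicate 1 (adjusted p = 0.155) or with the heart muscle mean as a covariate (0.55, adjusted p = 0.0719; chosen after seeing the data). Under quantile normalization the heart muscle list no longer passed (adjusted p = 0.130), and with median centring neither it (adjusted p = 0.0811) nor the lipid-associated macrophage list (0.46, adjusted p = 0.0828) did, although the heart muscle changes were larger there, at -0.79 and -0.66. With fry the adjusted p was 0.0175 for the lysosome and the lipid-associated macrophage list, but 0.533 for heart muscle. Exact permutation gave p = 0.00794 for each of the former (adjusted p = 0.0655) and 0.333 for heart muscle (adjusted p = 0.44). The heart muscle fall thus rests on camera at its preset correlation. The share of probe sets above 100 was higher in 14w-WD by 3.97 percentage points, as given above. Split by direction, the count was 686 higher and 304 lower under quantile normalization, of which 807 genes were shared with the 1338.

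All genes tested had a median log2 change of 0.23 in this comparison, and of 0.01 under quantile normalization. Each change given here is as fitted and is smaller by 0.23 relative to the median gene. On that footing the lysosome list averaged 0.42, the lipid-associated macrophage list 0.31 and the heart muscle list -0.81. The CHOW mean lay between the other groups for 1146 of the 1201 genes higher in 14w-WD, with a median log2 change of -0.61 from CHOW to 2w-WD and of 0.76 from CHOW to 14w-WD. It did so for 83.9% of the 137 lower genes and 54.9% of all genes tested, and genes picked for a difference between the outer groups favour a CHOW mean in between. The changed genes' score on each array, the summed level of the higher minus that of the lower genes divided by their number, went with the share of the 10587 other tested genes above an intensity of 100 (51.8% ± 3.12 in CHOW, 50.9% ± 4.74 in 2w-WD and 56.3% ± 3.00 in 14w-WD; SD, n = 5). Of all genes tested, 8.63% had no overlap between the 5 arrays of 14w-WD and the 5 of 2w-WD, where chance gives 0.794%.

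Over all genes tested 9 lysosome members rose, and adjusted over the list alone 15 did. Atp6v1a rose by a log2 of 2.57 (SE 0.45, adjusted p = 0.00850) and Gusb by 2.39 (SE 0.54, adjusted p = 0.0181). The protease genes Ctsk (1.08, SE 0.30), Ctsl (0.55, SE 0.12), Ctsd (0.55, SE 0.14) and Ctsb (0.27, SE 0.07), the acid lipase gene Lipa (0.61, SE 0.18), the membrane protein gene Lamp1 (0.37, SE 0.11) and Psap, which encodes activators of lipid breakdown (0.29, SE 0.09), rose with adjusted p from 0.0153 to 0.0421. In the lipid-associated macrophage list 4 members rose, 9 adjusted over the list alone: the tetraspanin gene Cd9 (2.42, SE 0.42, adjusted p = 0.00850), Ctsk, Ctsd and Plin2, which coats lipid droplets (0.37, SE 0.12, adjusted p = 0.0494). Under quantile normalization Lamp1 (0.27), Psap (0.22) and Plin2 (0.26) no longer passed. With median centring these 3 did not either, nor did Lipa (0.54) and Ctsb (0.20).

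Single members also changed in lists whose own test did not pass. Of the immunity-related GTPases, Ifi47 (log2 change 1.88), Irgm2 (1.85) and Irgq (0.85) rose (list mean 1.07, adjusted p = 0.0610, and 0.0269 under quantile normalization), and 4 rose adjusted over the list alone. Of the guanylate-binding proteins, Gbp6 (1.47, SE 0.40, adjusted p = 0.0314) and Gbp3 (1.33, SE 0.41, adjusted p = 0.0467) rose, though neither passed with a pseudocount of 1 (2.19, adjusted p = 0.0503, and 1.39), while Gbp7 (1.08, adjusted p = 0.0932), Gbp8 (0.34) and Gbp2 (0.25) did not pass (list mean 0.89, adjusted p = 0.180). Adjusted over that list alone 3 rose, again on genes the study chose on these samples. Gbp3 no longer passed under quantile normalization (0.89) or median centring (1.26). The immediate early genes Atf3 (1.99), Klf6 (2.17) and Ier5 (1.71) rose, with 17 of 17 members above 0 (list mean 0.79, adjusted p = 0.0619). The unfolded protein response had 5 members higher and 0 lower, led by Manf (1.32), the protein disulphide isomerase gene Pdia6 (2.09) and the chaperone gene Hsp90b1 (1.59), with a list mean of 0.67 (adjusted p = 0.0890). MHC class I presentation had 3 higher: the immunoproteasome genes Psmb10 (1.72) and Psmb8 (2.10) and H2-D1 (1.30, and 1.23 with median centring, where it did not pass), with a list mean of 0.87 (adjusted p = 0.103). The type I interferon response list had 3 higher, Bst2 (1.54), Ifit2 (2.44) and the RNA sensor gene Ifih1 (1.15), with a mean of 0.50 (adjusted p = 0.854).

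The inflammatory cytokine and NF-kB list did not pass (mean 0.57, adjusted p = 0.275), but held members that rose. Il1rn, an antagonist of interleukin-1, rose by 1.94, the NF-kB subunit gene Relb by 1.87 and the endotoxin receptor gene Tlr4 by 1.59, and 4 members in all rose. Il1b itself had a log2 change of -0.32 (SE 0.27, adjusted p = 0.415). Of the macrophage list 3 rose, Aif1 (1.82), the Fc receptor gene Fcgr3 (1.53) and the adaptor gene Tyrobp (0.38), with a list mean of 0.52 (adjusted p = 0.0619), while Cd68 (0.69, adjusted p = 0.156) and Adgre1 (0.14, adjusted p = 0.455) did not pass. Of the efferocytosis list Axl (1.69) and Dock1, a regulator of engulfment (1.82), rose and the receptor kinase gene Tyro3 (-0.71) fell (list mean 0.64, adjusted p = 0.180). Among chemokines and receptors Cxcl12 rose (1.14), with a list mean of 0.40 against a test direction of lower (adjusted p = 0.916). In the alternative activation list Folr2 rose (1.45), with a list mean of 0.16, which was -0.12 under quantile normalization (adjusted p = 0.763).

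Proliferation and lipid metabolism lists did not pass either, but held members that changed. Of the cell cycle list 5 rose, among them the replication clamp gene Pcna (2.03), the mitotic kinase gene Aurka (1.73) and Top2a (1.33), with a mean of 0.58 (adjusted p = 0.223). In sterol biosynthesis Cyp51 (1.41), Dhcr7 (1.47) and Lss (0.76), all enzymes of cholesterol synthesis, rose (mean 0.50, adjusted p = 0.726). Among liver X receptor targets Scd2 (1.63) and the lysosomal cholesterol carrier gene Npc2 (0.23) rose (mean 0.43, adjusted p = 0.334). In the lipid droplet list Lipa and Plin2 rose and Dgat2, an enzyme of triglyceride synthesis, fell by 1.04 (mean 0.16, which was -0.08 under quantile normalization, adjusted p = 0.886). In the glycolysis list Pfkp (1.81) and Pkm (1.30) rose (mean 0.37, adjusted p = 0.880), and in the oxidative stress list Gpx1 (0.48) rose (mean 0.19, which was -0.02 under quantile normalization, adjusted p = 0.916). Under quantile normalization the 3 sterol genes, Npc2, Gpx1, Tlr4, Fcgr3, Tyrobp, Cxcl12 and Ifih1 no longer passed, and with median centring Lss, Npc2, Gpx1 and Fcgr3 did not.

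Lists of other cell types were not called apart from heart muscle. Of the fibroblast list 4 rose, with Fbln1 (1.64), Fn1 (0.92) and Pdgfra (1.95) leading (mean 0.60, adjusted p = 0.180). Of the smooth muscle list Mylk rose (2.09), while Acta2 had -0.06 (mean 0.43, adjusted p = 0.930). Nos3 of the endothelium list rose (0.70, lost under quantile normalization and median centring; mean 0.19, adjusted p = 0.886), Ncr1 of the T and NK cell list fell by 0.87 (mean -0.01, adjusted p = 0.334) and Lep of the adipocyte list fell by 0.84 (mean 0.32, adjusted p = 0.211). In matrix remodelling Mmp3, a matrix protease, rose (2.25; mean 0.51, adjusted p = 0.334). In 9 of the uncalled lists, among them chemokines, alternative activation, lipid droplets, endothelium, adipocyte and the dendritic cell list (median -0.18), a mean above 0 went with a test direction of lower. No member changed in the lists of MHC class II presentation (mean 0.65), lipoprotein uptake (0.26), oxidative phosphorylation (0.16), B cell (0.25), dendritic cell (0.06), neutrophil (-0.42) and cartilage (0.43), whose adjusted p ran from 0.180 to 0.930. Heart muscle members with the smallest p were Ttn (-1.49, SE 0.83), Tnnt2 (-1.13, SE 0.76), Actn2 (-1.12, SE 0.76) and Pln (-0.67, SE 0.91), none of which passed.

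By size of change, the largest rises past the threshold were Exoc1, of the complex that tethers secretory vesicles (3.01, SE 0.73), Tmem38b (2.81, SE 0.60), Cspg4, a membrane proteoglycan (2.75, SE 0.68), Cmpk1, a nucleotide kinase (2.63, SE 0.50), Atp6v1a, Rnh1, an inhibitor of ribonucleases (2.44, SE 0.51), Ggh (2.44, SE 0.52), Ifit2 (2.44, SE 0.63), Cd9 and the zinc transporter gene Slc39a10 (2.40, SE 0.48). Their adjusted p ran from 0.00850 for Atp6v1a and Cd9 to 0.0270 for Ifit2. The largest falls were Kctd4 (-2.27, SE 0.57, adjusted p = 0.0235), the transcription factor gene Elf4 (-1.80, SE 0.36, adjusted p = 0.0123), Ccnjl (-1.50, SE 0.37), Sbsn (-1.48, SE 0.40), Fam83e (-1.47, SE 0.42), Celf4 (-1.40, SE 0.40), Hlf (-1.38, SE 0.32), Ddx10 (-1.33, SE 0.39), Gdf11 (-1.27, SE 0.40) and Camk2d, a calcium-dependent kinase gene (-1.23, SE 0.32). When the probe sets of Camk2d were averaged its change was 0.14, so its probe sets did not go the same way.

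The count of 1338 was 0 with the share of probe sets above 100 as a covariate (which counts the changed genes too, and with which the lysosome list, at 0.41, and the lipid-associated macrophage list, at 0.38, still passed) and 206 without CHOW replicate 4 and 2w-WD replicate 4, both settings chosen after seeing the data. It was 3536 without 2w-WD replicate 1 and 164 without 14w-WD replicate 1, 224 without 14w-WD replicate 3, 260 without 2w-WD replicate 2, 260 without 2w-WD replicate 4, 568 without 14w-WD replicate 5, 628 without 14w-WD replicate 2 and 721 without 2w-WD replicate 3.

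**Figure D3:**
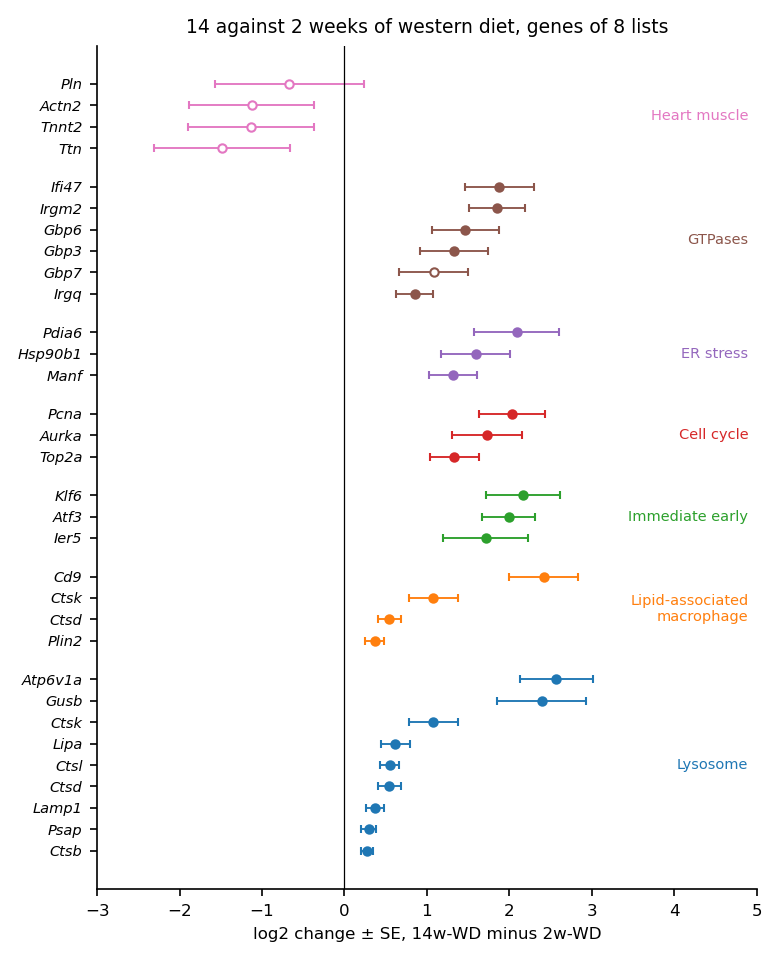
Log2 change from 2w-WD to 14w-WD (points, with SE as bars) of named genes from 8 lists, grouped by list; filled points passed an adjusted p of 0.05 and open points did not. The guanylate-binding proteins and immunity-related GTPases share a group. Changes are as fitted, and the median gene lies at 0.23; Lamp1, Psap, Plin2 and Gbp3 no longer passed under quantile normalization or median centring, nor did Lipa and Ctsb with median centring, and neither scaling turned a filled point.

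Taken over both western diet groups against CHOW, limma called 0 genes, with 726 at an unadjusted p under 0.05 (433 higher, 293 lower) and a smallest adjusted p of 0.336. The F test over the 3 groups called 312 genes, with 3038 at an unadjusted p under 0.05. Of the 15 arrays 12 moved this count by over 1.5 times when left out, to 890, 124 and 137 without CHOW replicates 1, 2 and 3, to 2258, 27, 44, 38 and 65 without 2w-WD replicates 1 to 5, and to 5, 43, 5 and 23 without 14w-WD replicates 1, 2, 3 and 5. The 2w-WD and 14w-WD changes against CHOW correlated across the tested genes at r = 0.04, where genes are not independent replicates. Unchanged groups set against the same CHOW arrays gave a median r of 0.52 in 1000 simulations (95% of them between 0.08 and 0.80). The covariance was 0.00808 against a simulated median of 0.0501, a difference of -0.0420. It lay inside the range of 95% of the simulations (0.00498 to 0.128), whereas r lay below its range, so the 2 measures differ on this. With the CHOW arrays split between the comparisons the median r was -0.16 over 20 splits (-0.47 to 0.22).

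**Figure D4:**
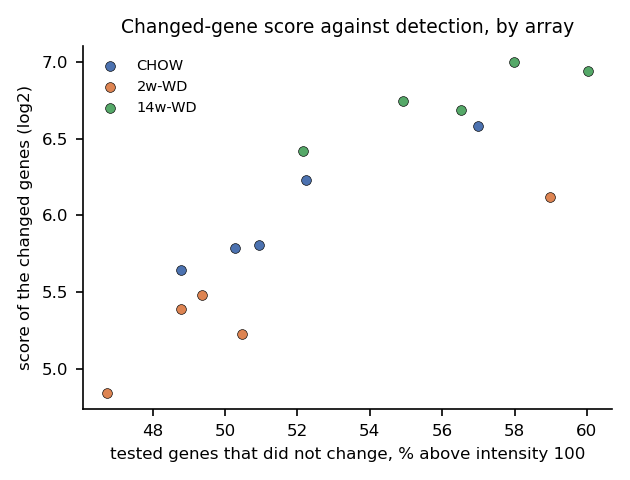
Score of the changed genes (log2) on each of the 15 arrays (points coloured by group). It is set against the percentage of the other tested genes, those not called as changed, lying above an intensity of 100. Arrays with more of these other genes above 100 have higher scores; within groups r = 0.919.

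**Figure D5:**
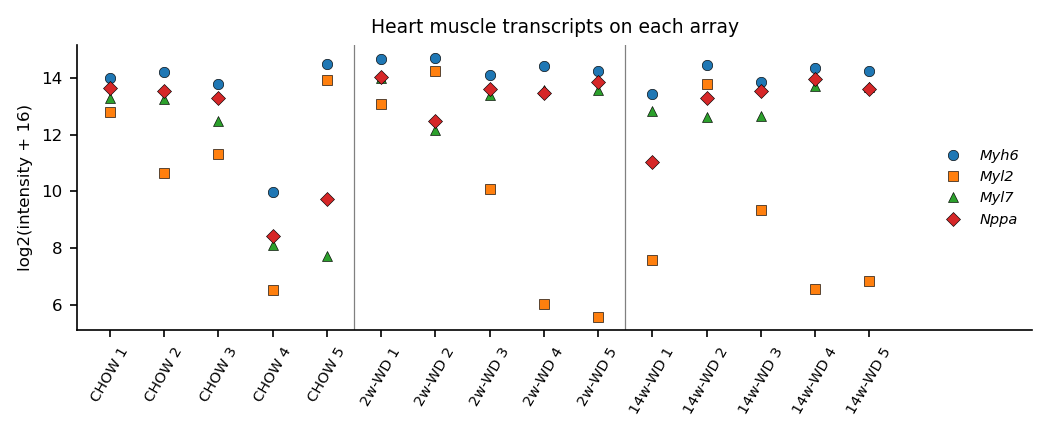
Log2(intensity + 16) of 4 heart muscle genes on each of the 15 arrays, grouped by diet; where points coincide, Nppa covers Myl7. Myh6 is near 14 on every array except CHOW replicate 4 (9.98), while Myl2 ranges from 5.56 to 14.26.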

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

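The splits of the arrays, the test of detection over genes not called, the heart muscle covariate, the tests of the heart muscle list and the leave-one-out test and the adjustment for detection of the GTPase lists were chosen only after the results were seen. The other tests were written down before. There the score of the changed genes was first worded as the mean of the higher minus the mean of the lower genes, while each gene counts equally in the score used here.

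Of 150 group measures looked at, 13 had an array far from the other 4 of its group, where chance flags about 1 in 20 groups, or 7.5. The 75th percentile of intensity was 104.3 on 2w-WD replicate 1 (others 74.05 to 81.31), and the 100 brightest probe sets held 10.99% of the signal on CHOW replicate 5 (others 10.73% to 10.8%). In 14w-WD, replicate 4 was lowest in the means of the MHC class I presentation list (8.64; others 9.25 to 9.37), the efferocytosis list (9.92; others 10.33 to 10.48) and the smooth muscle list (7.80; others 8.89 to 9.13) and in Acta2 (12.33; others 13.20 to 13.51). Replicate 2 of 14w-WD was highest in the oxidative phosphorylation list (11.68; others 11.14 to 11.22). In 2w-WD, replicate 1 was highest in the alternative activation list (8.43; others 7.06 to 7.38) and replicate 5 in Acta2 (13.38; others 13.17 to 13.22). In CHOW, replicate 5 was lowest in the lysosome list (12.61; others 12.81 to 12.88), replicate 2 highest in the B cell list (8.30; others 7.58 to 7.78), replicate 4 lowest in Myh6 (9.98; others 13.81 to 14.50) and replicate 1 lowest in Abca1 (11.72; others 12.54 to 12.76).

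The changes after 2 and after 14 weeks, both against CHOW, differed for 1338 genes. By camera they also differed for the lysosome (0.65), lipid-associated macrophage (0.54) and heart muscle (-0.58) lists. Of the genes named against CHOW, the difference of 14w-WD minus 2w-WD passed for Atf3 (1.99), Fam102a (2.01), Il1rn (1.94), Panx1 (1.69), Sptlc2 (1.47), Ankhd1 (1.30), Cacybp (1.55), Mfsd14b (1.72), Nin (2.04) and Galnt7 (1.80), and on the lower side for Pifo (-0.71), Gatd1 (-1.07), Hecw2 (-0.91), Slc8a3 (-0.65) and Tex15 (-0.95). Among 4079 bright probe sets without a gene name, 115 changed between 14w-WD and 2w-WD, 80 higher and 35 lower.

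The genes changed between 14w-WD and 2w-WD were mostly higher in 14w-WD, with a difference in their score per array of 1.35 (SE 0.24), or 2.30 (SE 0.36) as first worded. The score holds genes called for this same difference on these arrays. Its differences here, adjusted or not, are therefore large in part by selection, and their SEs do not allow for that. Adjusted for detection over 10092 probe sets without exactly 1 gene, the difference was 1.41 (SE 0.20), or 2.38 (SE 0.33) as first worded. Within groups the score and that share had r = 0.599 (permutation p = 0.0423, adjusted p = 0.0564). By rank rho was 0.439 (permutation p = 0.133), and r was 0.401 without the 2 farthest arrays. That share was 14.4% in 2w-WD and 14.2% in 14w-WD, so adjusting for it could hardly lower the difference. This test therefore does not decide whether array-wide detection of weak transcripts accounts for the difference. Detection of moderately abundant transcripts may account for part. Adjusted for the share above 100 of the tested genes not called, the difference was 0.84 (SE 0.12), 62.4% of the unadjusted one, or 65.2% as first worded. Within groups the score followed that share (r = 0.919, permutation p = 9e-05, adjusted p = 0.00036). By rank rho was 0.864 (permutation p = 0.00026), and r was 0.811 without the 2 farthest arrays, with 4 relations in the family. These genes only missed the threshold, and 2653 genes passed at an adjusted p under 0.10, so the adjustment may also remove part of the difference itself. The heart muscle list mean as a covariate did not remove it, as 85.0% of the genes were still called. The balance of heart muscle genes differed between arrays, so their mean need not measure the amount of heart muscle. A part played by heart muscle is therefore not excluded. Without 2w-WD replicate 4, the lowest, the median change kept 88.3%, but over genes picked with all arrays, and the count was 164 without 14w-WD replicate 1, so the part of a single array stays open, as does whether the remaining 0.84 reflects the diet or the RNA of these arrays.

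Heart muscle transcripts were higher in 2w-WD than in CHOW by a mean log2 of 1.21. Without CHOW replicate 4 the difference was 0.47, so a single array may carry much of it, although the list still passed (adjusted p = 0.00292). The heart muscle genes varied together within groups, with a median r of 0.590 between genes against 0.159 in 1000 random lists of like level (95% of them between 0.00447 and 0.357), in line with heart muscle in the captured tissue that differs by array. These tests do not tell whether the diet groups differ in it.

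The guanylate-binding proteins and immunity-related GTPases, 11 genes, were higher in 14w-WD than in CHOW by a mean of 0.92 (SE 0.26). The mean stood at percentile 100 of 10000 random lists of the same size and level (median 0.13, 95% of them between -0.13 and 0.41), but this restates the lists' own test and ignores the correlation between members. Adjusted for detection over probe sets without exactly 1 gene the difference was 0.89 (SE 0.25). That share was 13.9% in CHOW and 14.2% in 14w-WD, so adjusting for it could hardly lower the difference. Adjusted for detection over genes not called between 14w-WD and 2w-WD the difference was 0.65 (SE 0.25). Array-wide detection may thus account for part of it, and whether it accounts for more was not settled. Leaving out 14w-WD replicate 5, the most influential array, kept 77.9% of it (0.72), so the share of a single array cannot be told apart from biological spread here. The study reported on guanylate-binding proteins in these samples, so their direction is no independent evidence.

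Each count was set against 99 other splits of the arrays it compares, so the numbers below are of 100 splits with the real included. For 2w-WD versus CHOW and for both western diet groups against CHOW the real gene count was 0, which every split reaches, so that 100 of 100 in both tests nothing; the highest other counts were 527 and 2316. As many lists as in 2w-WD versus CHOW (9) came in 4 splits, with up to 10. As many genes as in 14w-WD versus CHOW (1) came in 7, with up to 672, and as many lists (2) in 80, with up to 9. As many genes as in 14w-WD versus 2w-WD (1338) came in 2, with 3071 in the other, and as many lists (3) in 65, with up to 13. As many genes as in the F test (312) came in 1, with 5 as the highest other. The split with 3071 genes set 2w-WD replicate 1 with 14w-WD replicates 1, 2, 3 and 5, and so keeps most of each diet group together. Its gap in probe sets above 100 was 5.28 percentage points, against 3.97 between the real groups, but 3 splits, itself included, had a gap larger than the real groups, and gap and gene count were only loosely related over the 99 splits (rho = 0.297, not tested). Counts well above the real one point to a structure of the samples that the groups do not capture in full, and what it is was not settled.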

How the results depend on the processing

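The covariates (share of probe sets above 100, called detection here, and heart muscle list mean), the fit without the 3 arrays of lowest weight and the fit without CHOW replicate 4 and 2w-WD replicate 4 were chosen only after the results were seen. Over named genes and settings, 10368 cases kept their side of the threshold, 257 newly passed, 596 no longer passed and 1 that had passed turned; for lists, by the direction of the test, these numbers were 3154, 69, 124 and 1. Most of these genes and lists had not passed with all arrays and had no call to lose, so the kept cases do not measure how often calls were kept. The value itself changed sign in 65 gene and 98 list cases, of which 1 and 2 had passed with all arrays. Camk2d in 14w-WD versus 2w-WD turned to 0.14 with the mean of its probe sets, and oxidative phosphorylation in 2w-WD versus CHOW to -0.13 with the heart muscle covariate. Signal over background limits dim genes (filter at intensity 34.6). The 3-prime to 5-prime covariate was not run. Beyond fewer arrays, other gene numbers or another threshold, the cause was not tested.

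In 2w-WD versus CHOW the gene count was 0 in every setting. The 9 lists became 5 with the heart muscle covariate, 5 without CHOW replicate 4 and 2w-WD replicate 4, and 0 with camera's estimated correlation, 0 with fry and 0 by exact permutation; leaving out 1 array gave 6 to 9. No single array ended the lysosome, efferocytosis or heart muscle call. Calls ended for oxidative phosphorylation without 2w-WD replicates 1 (mean change -0.09) or 2, lipid-associated macrophages without 2w-WD replicate 1, immediate early genes without CHOW replicate 5 or 2w-WD replicates 2 or 4, macrophages without CHOW replicate 2 or 2w-WD replicate 1, the unfolded protein response without CHOW replicates 4 or 5 or 2w-WD replicates 2, 3 or 4, and chemokines without CHOW replicates 1, 2 or 5 or 2w-WD replicates 3, 4 or 5.

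In 14w-WD versus CHOW the count of 1 gene became 0 under quantile normalization, 17 without a filter, 0 with the stricter filter, 0 with the mean of all probe sets, 2234 with array weights, 122 with only the 2 groups, 87 at an adjusted p under 0.10, 0 with the detection covariate, 1353 without the 3 arrays of lowest weight and 19 without CHOW replicate 4 and 2w-WD replicate 4. The stricter filter left Galnt7 and the 2 GTPase lists untested, and 0 other lists passed. Leaving out 1 array gave 0 to 201: 17 without CHOW replicate 1, 0 without CHOW replicates 2, 3 or 5, 4 without CHOW replicate 4, 201 without 2w-WD replicate 1, 8 without 2w-WD replicate 4, and 0 without 14w-WD replicates 1, 3 or 5. The 2 lists became 0 without a filter, with array weights, only 2 groups, a pseudocount of 1, an estimated correlation, fry or exact permutation. They became 6 with the detection and 4 with the heart muscle covariate, and 1 without the 3 arrays of lowest weight. Leaving out 1 array gave 0 to 3 lists: 1 without CHOW replicates 1 or 3, and 0 without CHOW replicate 2, 2w-WD replicates 1, 3 or 4, or 14w-WD replicate 5. The guanylate-binding proteins also lost their call without CHOW replicates 1 or 3 or 14w-WD replicate 4, and the immunity-related GTPases without CHOW replicates 3, 4 or 5.

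In 14w-WD versus 2w-WD the 1338 genes became 3839 with array weights, 2653 at an adjusted p under 0.10, 0 with the detection covariate, 3175 without the 3 arrays of lowest weight and 206 without CHOW replicate 4 and 2w-WD replicate 4. Leaving out 1 array gave 164 to 3536: 3536 without 2w-WD replicate 1, 260 without 2w-WD replicate 2, 721 without 2w-WD replicate 3, 260 without 2w-WD replicate 4, 164 without 14w-WD replicate 1, 628 without 14w-WD replicate 2, 224 without 14w-WD replicate 3 and 568 without 14w-WD replicate 5. The 3 lists became 1 with median centring, 5 without a filter, 7 with the mean of all probe sets, 1 with array weights, 7 at an adjusted p under 0.10, 7 with the detection covariate, 1 with the heart muscle covariate, 1 without the 3 arrays of lowest weight, 0 with an estimated correlation, 15 with fry and 0 by exact permutation. Leaving out 1 array gave 1 to 6 lists: 6 without CHOW replicate 1, 1 without 2w-WD replicate 1, 6 without 2w-WD replicate 5, and 5 without 14w-WD replicates 2 or 4. No array ended the lysosome call; the lipid-associated macrophage call ended without 2w-WD replicate 1 and the heart muscle call without any of 4 arrays. Of 76 passing named genes, 61 still passed under quantile normalization, 64 with median centring, 0 with detection and 70 with heart muscle as covariate. None turned in these settings.

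With both western diet groups against CHOW, 2 genes passed without the 3 arrays of lowest weight, and 0 in every other setting. The F test's 312 genes became 95 under quantile normalization, 186 without a filter, 175 with the stricter filter, 3602 with array weights, 1245 at an adjusted p under 0.10, 189 with a pseudocount of 1, 0 with the detection covariate, 2462 without the 3 arrays of lowest weight and 40 without CHOW replicate 4 and 2w-WD replicate 4. Leaving out 1 array gave 5 to 2258: 890, 124 and 137 without CHOW replicates 1, 2 and 3, 2258, 27, 44, 38 and 65 without 2w-WD replicates 1 to 5, and 5, 43, 5 and 23 without 14w-WD replicates 1, 2, 3 and 5. The correlation of the 2w-WD and 14w-WD changes, 0.04 with all arrays, was -0.16 with the CHOW arrays split and ran from -0.18 (without 2w-WD replicate 1) to 0.17 (without CHOW replicate 1).

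With the replicate number as a block, 20 genes and 0 lists passed in 14w-WD versus CHOW, 2122 genes and 5 lists in 14w-WD versus 2w-WD, and 996 genes in the F test. Whether the numbers pair the samples was not settled, since no chance level was worked out for the values that follow. Deviations of same-numbered arrays correlated at -0.17 to 0.48, 7 of 15 pairs over 0.1, and 6 of 15 arrays best with their own number.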

Other observations

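No test in this part was chosen after a result was seen, but the genes named here were picked from the heart muscle list after their values were seen. The balance of heart muscle transcripts differed between arrays. Myl2, the light chain of ventricular muscle, reached 13.95 on CHOW replicate 5 and 14.26 on 2w-WD replicate 2, but 6.02 on 2w-WD replicate 4, 5.56 on 2w-WD replicate 5, 6.54 on 14w-WD replicate 4 and 6.84 on 14w-WD replicate 5. Myl7, the light chain of atrial muscle, was at 7.73 and 12.16 on the former and at 13.59, 13.57, 13.71 and 13.67 on the latter. Other arrays had high levels of both Myl2 and Myl7: 12.79 and 13.29 on CHOW replicate 1, 13.09 and 14.00 on 2w-WD replicate 1 and 13.78 and 12.63 on 14w-WD replicate 2. Myh6, the myosin heavy chain of adult mouse heart, lay between 13.43 and 14.69 on all arrays except CHOW replicate 4 (9.98), where Nppa, the atrial natriuretic peptide gene, was at 8.42 and Myl2 at 6.51.

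Outside the lists' own tests, members with the smallest p in 14w-WD against CHOW included Folr2 (log2 change 1.23, SE 0.33, adjusted p = 0.123), Klrk1 (-1.41, SE 0.39, adjusted p = 0.133), H2-DMb2 (1.11, SE 0.32, adjusted p = 0.136), Fbln1 (1.20, SE 0.35, adjusted p = 0.144), Cyp51 (1.31, SE 0.40, adjusted p = 0.149) and Il18 (0.76, SE 0.23, adjusted p = 0.152). In 2w-WD against CHOW they included Chil3, a secreted protein of alternatively activated macrophages (1.90, SE 0.48), and Fn1, fibronectin (-0.87, SE 0.21), both with an adjusted p of 0.480 over all genes; adjusted over the list alone 1 alternative activation member was higher and 1 fibroblast member lower.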
